A study of Homo sapiens with 6 samples.

How the data were processed

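The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) in PDX2 cells, human B-cell acute lymphoblastic leukaemia (B-ALL) cells. Of its 6 samples, 4 have a list of peaks and are used here. The remaining 2 samples, the inputs of the cells with each form of the TET1 catalytic domain, are not analysed here. STAT5B was immunoprecipitated from control cells (sgNS) and from cells in which TET1 was knocked out (sgTET1). A Flag-tagged catalytic domain of TET1 (TET1-CD) was immunoprecipitated with an antibody against Flag from cells expressing its wild-type form (WT) or a mutant form (MUT). The labels do not name the mutation. Groups were taken from the sample titles. There was 1 library per condition. No test between conditions was therefore made and no p-value is given for any difference between them. Intervals cover counting error only, for regions or fragments in these libraries, and say nothing of the spread between cultures.

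Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 minutes, libraries were amplified with 10 cycles of PCR, and single-end reads of 50 nt were obtained. FastQC, Bowtie2 2.3.2, Picard 2.21.1, MACS2 2.2.7.1, HOMER and deepTools 3.5.1 and the genome build hg38 are named, per the submitters' processing notes. Their order and settings, and whether an input served as control for each list, are not given in the sources used here. The names of the peaks carry the mark rep1 in both STAT5B lists and rep2 in both TET1-CD lists. Each list is therefore taken here as called on 1 library, and no list from another replicate of either was available here. Each deposited row gives the position of a peak, a score equal to 10 times the −log10 p and cut to a whole number, the fold enrichment of the summit over the background, the −log10 p, the −log10 q and the summit. The fold, which is a ratio, and the p-value and q-value are those the authors' peak caller gave. They are used here only to describe, rank or filter peaks within a list, apart from the fragment heights described next. The smallest −log10 p was 2.09 in the STAT5B sgNS list, 2.15 in the STAT5B sgTET1 list, 2.50 in the TET1-CD WT list and 2.02 in the TET1-CD MUT list, while q was 1 for 74.3% of the sgNS and 75.5% of the sgTET1 regions. The deposited lists were thus filtered on p and not on q.

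In each list, the fold enrichments fell on 1 evenly spaced ladder. They were reproduced by a whole number of fragments at the summit, 1 scale and 1 background for the whole list, with a pseudocount of 1. All heights were whole within 0.05 fragments. The p of each peak followed from the same height and background as a Poisson upper tail within 0.01 −log10 units, except for 1 TET1-CD WT region. The solved background was 3.30 fragments for sgNS, 3.19 for sgTET1, 1.49 for WT and 1.66 for MUT, and the scale per fragment was 0.516, 0.520, 0.936 and 0.491. The height of a region is given below as this number of fragments, with an exact Poisson interval. The total number of reads per library is not given in the sources used here. The background, in fragments, is the measure of depth used in its place.

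Rows on chromosomes 1 to 22 and X were kept, which left out 480, 527, 727 and 646 rows of the sgNS, sgTET1, WT and MUT lists. No rows in a list shared bases, so none were merged. The gene table used here (GRCh38, the assembly also called hg38) gives the start and end of each gene but not its strand, and no genome sequence was used. A region was therefore assigned to a gene when it overlapped the 1 kb on either side of either annotated end of the gene, in place of the planned window around the transcription start. The table held 19970 protein-coding genes on these chromosomes, and all 178 genes of the lists matched. Motif and CpG content at summits were planned and not run. Random gene lists were matched on gene length in 10 bins in place of promoter CpG density.

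Lists were compared by overlap of at least 1 bp. The share of overlapped regions was set against 200 circular shifts of the query regions within each chromosome. It was also set against 20 sets (100 for the strongest STAT5B regions) in which each region moved by 10 to 50 kb to either side. This local shift was added after the data were examined, since regions of all lists cluster along chromosomes. Shares carry exact Clopper-Pearson 95% intervals. Retention of STAT5B sgNS regions in the sgTET1 list was compared between regions with and without an overlapping TET1-CD WT region. The difference was averaged with equal weight over deciles of −log10 q, tied values kept together, with at least 20 regions of each kind per decile. Its interval comes from a jackknife over chromosomes and covers variation along the genome only. For 14 gene lists fixed before the data were examined, the number of members with a region was placed among 10000 random lists, as a description of these libraries. Numbers of genes shared by independent lists were computed within chromosomes 8 and 18 and within the other chromosomes, a choice made after the values were seen. Intervals, overlaps, shifts and list draws were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

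The genes named were fixed by a rule before the data were examined. It takes CD72, JCHAIN, TET1, STAT5A and STAT5B always, of which CD72 and JCHAIN were known as genes of the study and are not independent evidence. It adds the 6 genes with the highest fold at a gene end in each list, and per pair and direction the 6 highest with no region within 1 kb in the other list. It also takes up to 4 members of each gene list and the 3 highest regions away from gene ends in each list. Genes that share an end within 1 kb are named together. Other genes named were chosen after their values were seen, and the text says so. Alternatives planned before the data were examined were a −log10 q of 5 or more, lists cut to equal length by −log10 q, a window of 2 kb, coverage of 50% of the region, summits within 200 bp, and other strata of the retention difference. Equal length was that of the shortest of the 4 lists for gene ends, gene lists and retention. For overlaps it was that of the shorter list of the pair. Leaving out chromosomes 8 and 18, a q of 0.05 or less, matched height limits, and STAT5B regions of 20 or more fragments, by themselves and within 10 kb of a gene, were chosen after seeing the data. In both STAT5B lists, regions of 20 or more fragments were the same number as those at a q of 0.05 or less.

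The functions were tested on simulated data. Heights made with 3 settings of background and scale were recovered for 100% of 60000 regions each. Of the 50414 sgNS values scattered by up to 10%, 9.36% came out whole. Of 300 regions compared with a direct search, 300 had the same overlap call. For a planted overlap of sgNS with TET1-CD WT expected at 36.4%, 37.3% was found. A planted retention difference of 15 percentage points over the 50414 sgNS regions was found as 15.2, and one of 0 as −0.0432. Over the 19970 genes with their sgNS calls, 2.5% of random lists lay at percentile 97.5 or above, and 76% of lists in which called genes were 6 times as likely to be drawn did.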

Results

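Binding of STAT5B, a transcription factor activated by cytokine receptors and JAK kinases, and of the catalytic domain of TET1, an enzyme that oxidises 5-methylcytosine in DNA, was mapped by ChIP-seq in PDX2 B-ALL cells. Per the series title, the purpose was to chart where both proteins bind across the genome. The 4 lists came from 1 library each, so no difference between conditions below has a replicate check. STAT5B was mapped in control cells (sgNS) and TET1-knockout cells (sgTET1), and the Flag-tagged TET1 catalytic domain in its wild-type (WT) and mutant (MUT) form. The lists do not measure TET1 abundance and so do not check the knockout. On chromosomes 1 to 22 and X, the STAT5B sgNS list held 50414 regions covering 13.1 Mb and the sgTET1 list 35096 regions covering 8.77 Mb. The TET1-CD WT list held 479546 regions covering 122 Mb and the MUT list 331525 regions covering 92.6 Mb. Most regions were low, with a median height of 14 fragments in both STAT5B lists, 10 in WT and 11 in MUT. The smallest heights listed were 10, 10, 6 and 7 fragments in sgNS, sgTET1, WT and MUT. At a q of 0.05 or less there remained 1703 sgNS, 986 sgTET1, 477905 WT and 109170 MUT regions.

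The first comparison asked how STAT5B binding differed between control and TET1-knockout cells. The highest STAT5B regions at gene ends in control cells included known targets of STAT5 signalling, and no region was listed within 1 kb of them in TET1-knockout cells. The highest was at BCL6, a transcriptional repressor of germinal-centre B cells (chromosome 3, 187745227 to 187745909, hg38), with 60 fragments (Poisson 95% interval 45.8 to 77.2) and a fold of 11.8. A region of 48 fragments (35.4 to 63.6) lay at the shared end of CISH, a feedback inhibitor of cytokine signalling, and MAPKAPK3, a stress-activated kinase (chromosome 3, 50611826 to 50612197). SOCS2, another feedback inhibitor of JAK and STAT signalling, had a region of 43 fragments (chromosome 12, 93570755 to 93571075). KLF7, a zinc-finger transcription factor, had one of 48 fragments (chromosome 2, 207074271 to 207074862), and SLFN12L, a member of the Schlafen family, one of 45 (chromosome 17, 35537599 to 35537895). How high these places stood in sgTET1 is not known exactly, since the list gives no height where it has no region. The smallest height listed in sgTET1 was 10 fragments.

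Of the 14 genes in the preset list of STAT5 targets, 6 had a region at a gene end in sgNS (BCL6, CISH, SOCS2, MYC, SOCS3 and MCL1), against 1.52 in random lists of the same gene lengths (percentile 99.8). In sgTET1, 1 of the 14 had one (MYC; random mean 0.413, percentile 79.7). With STAT5B regions of 20 or more fragments in the gene or within 10 kb, a criterion chosen after the values were seen, 8 of 14 had a region in sgNS (random mean 0.286, percentile 100) and 1 of 14, MYC, in sgTET1 (percentile 95.9). The sgNS genes included BCL2L1, an inhibitor of apoptosis, with 46 fragments inside the gene (chromosome 20, 31675791 to 31676147). They also included PIM1, a survival kinase, with 41 fragments (chromosome 6, 37183236 to 37183530, outside genes) and CCND3, a D-type cyclin, with 31 fragments inside the gene (chromosome 6, 41936146 to 41936410). The sgTET1 list held 0 regions in or within 10 kb of CISH, SOCS3, PIM1, BCL2L1 and CCND3. At MYC, a driver of cell growth on chromosome 8, both lists had regions of similar height, 24 fragments (15.4 to 35.7) in sgNS and 23 (14.6 to 34.5) in sgTET1. Without chromosomes 8 and 18 the gene-end counts were 5 in sgNS and 0 in sgTET1, out of 13 genes, and at a −log10 q of 5 or more they were 3 and 0 out of 14.

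**Figure D1:**
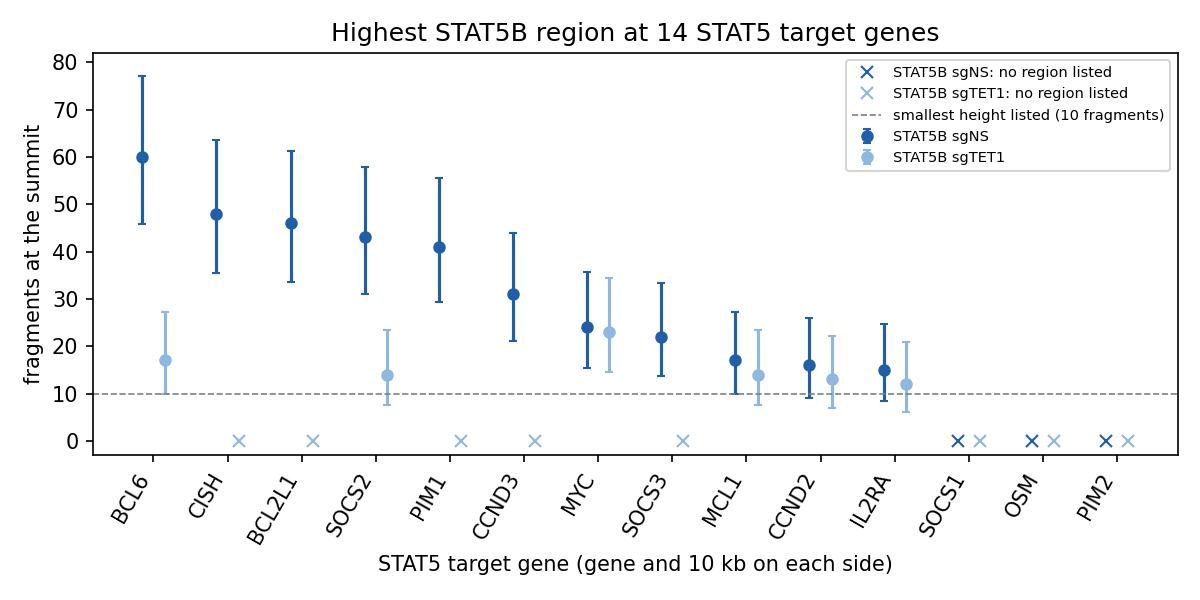
Fragments at the summit of the highest STAT5B region in each of 14 STAT5 target genes or within 10 kb of it, in control (sgNS, dark) and TET1-knockout (sgTET1, light) cells; bars are Poisson 95% intervals for counting error in 1 library each, crosses at the bottom mark genes with no region listed, and the dashed line is the smallest height listed, 10 fragments. BCL6, CISH, BCL2L1, SOCS2, PIM1 and CCND3 reach 31 to 60 fragments in sgNS and at most 17 in sgTET1, while MYC has 24 and 23.

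In sgNS, each other preset list had a smaller share of its genes with a gene-end region. Of 15 apoptosis genes, 5 had a gene-end region in sgNS (percentile 99.0) and 2 in sgTET1 (BCL2 and BID; percentile 96.4). Without chromosomes 8 and 18, the second of which carries BCL2, these counts were 4 of 13 (97.8) and 1 of 13 (88.75) against random lists from the other chromosomes. Of 15 housekeeping and ribosomal genes, 5 had one in sgNS (percentile 98.7) and 0 in sgTET1. Of 12 cytokine receptor and JAK signalling genes, 3 had one in sgNS (PTPN6, IL7R and SH2B3; percentile 92.1) and 0 in sgTET1. At a −log10 q of 5 or more, 0 genes of these 3 lists had one in either library. By the criterion of 20 or more fragments within 10 kb, 2 of 15 apoptosis genes (percentile 98.05) and 2 of 15 housekeeping and ribosomal genes (98.65) had a region in sgNS, and 1 (95.05) and 0 in sgTET1. By it, 1 of 22 B-lineage genes (72.1) and 1 of 15 tissue-restricted genes (88.4) had a region in sgNS, and 0 of either in sgTET1. Among 22 B-lineage genes the counts were 2 in sgNS (IKZF1 and CD22; percentile 48.2) and 0 in sgTET1. Of the cell cycle genes, 1 of 16 had one in each list, MCM2 in sgNS and MKI67 in sgTET1. In sgNS, 0 of 12 DNA methylation genes (percentile 13.7), 0 of 6 HOXA and MEIS1 genes (30.05) and 0 of 15 CpG-island developmental genes (8.57) had one. The counts in sgTET1 were 0, 0 and 1 (NEUROG1). Among markers of other cell types the sgNS counts were 0 of 12 T and NK cell (percentile 11.9), 0 of 11 myeloid (14.1), 0 of 8 erythroid (22.6) and 0 of 15 tissue-restricted genes (7.92), within the range of random lists. In sgTET1 these counts were 1 (CD8A), 0, 0 and 0.

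CD72, which encodes a B-cell surface co-receptor, had 4 STAT5B regions in the gene or within 10 kb in sgNS and 0 in sgTET1. The highest had 16 fragments (9.15 to 26.0; chromosome 9, 35620623 to 35620799), with a −log10 q of 0.209. JCHAIN, which encodes the joining chain of secreted antibodies, had 0 in both lists. TET1 had 0 in sgNS and 1 of 12 fragments in sgTET1, STAT5A had 1 and 0, and STAT5B had 3 and 1, none above 17 fragments.

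In the sgTET1 list the highest gene-end region was at NBPF1 (28 fragments; chromosome 1, 16614200 to 16615077), a member of a multi-copy family whose copies can share reads, and all 4 lists had regions there. SLC14A1, a urea transporter, had 23 fragments. MCM4 (which shares an end with PRKDC), RPL8 and SLA had 22, and BOP1 (which shares an end with MROH1 and HSF1) had 21. Apart from NBPF1 these lay on chromosomes 8 and 18, and each had an sgNS region within 1 kb. With no sgNS region within 1 kb, the highest sgTET1 gene-end regions were at CLVS1 with 21 fragments and SHISA2 with 19. ANKRD29, ANTKMT with CCDC78, and ERICH5 followed with 18 each, a height also reached at NEUROG1 and at SDCBP2 with SNPH. The 3 highest regions away from gene ends were the same places in sgNS and sgTET1, beside the centromeres of chromosomes 16 and 3. In sgNS they were chromosome 16, 46389511 to 46391192 (291 fragments; nearest gene SHCBP1) and 46394350 to 46395344 (238; SHCBP1), and chromosome 3, 93470242 to 93470907 (236; PROS1), with regions within 1 kb in all 4 lists.

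Over all regions, sgTET1 overlapped 19.6% of sgNS regions (19.2 to 19.9), against 3.66% for circular shifts and 10.8% for local shifts. In the other direction 28.5% of sgTET1 regions were overlapped. These shares were 61.2% of 183 and 77.0% of 148 regions at a −log10 q of 5 or more. Many of the strongest shared regions were places listed with both antibodies. Outside chromosomes 8 and 18, 130 sgNS regions of 30 or more fragments were in both STAT5B lists, and 109 of them overlapped both TET1-CD lists. The higher shares therefore do not show that STAT5B binding was kept without TET1. Chromosomes 8 and 18 held 52.0% of sgNS and 73.1% of sgTET1 regions, a density 13.5 and 33.8 times that of the other chromosomes. There the lists had 26233 and 25659 regions, a ratio of 1.02. On the other chromosomes they had 24181 and 9437, a ratio of 2.56, and the overlap was 4.93% of sgNS regions (local shifts 1.00%) and 12.9% of sgTET1 regions. The contrast depended on height. At 20 or more fragments the ratio of sgNS to sgTET1 regions was 1.85 on chromosomes 8 and 18 and 1.54 on the others. At 30 or more it was 4.25 (17 and 4 regions) and 1.23. The background was similar, at 3.30 fragments in sgNS and 3.19 in sgTET1. On these other chromosomes, 6.89% of sgNS regions lay at a gene end (6.57 to 7.21), above the 4.86% of local shifts. In sgTET1 it was 3.05% (2.71 to 3.42), below the 4.08% of local shifts. Protein-coding genes with an end region numbered 2062 in sgNS and 568 in sgTET1, of which 288 were shared, where lists independent within chromosomes 8 and 18 and within the others would share 127.

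Of the 589 sgNS regions of 20 or more fragments outside chromosomes 8 and 18, 341 were also in the sgTET1 list and 248 were not. Of the 383 such sgTET1 regions, 340 were also in sgNS and 43 were not. Among those in 1 list only, 27 of the 248 sgNS regions and 0 of the 43 sgTET1 regions lay at a gene end. With the limit at 30 fragments, 36 sgNS regions and 1 sgTET1 region were in 1 list only.

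The second comparison set the wild-type catalytic domain of TET1 against its mutant form. In the full lists, both had a region at an end of most genes. Of 19970 protein-coding genes, 14767 had an end region in WT and 14499 in MUT, and 13373 had one in both, where lists independent within the same 2 sets of chromosomes would share 10728. All 14 STAT5 targets had one in WT (random mean 10.3, percentile 99.3) and in MUT (percentile 99.5). So did 14 of 15 apoptosis genes (percentile 94.4 and 96.1) and 15 of 16 cell cycle genes (96 and 97.3) in each list. The random lists were matched on gene length only. These percentiles therefore do not account for promoter CpG content or gene activity. Fewer tissue-restricted non-blood genes than in random lists had one in WT, 7 of 15 against 11.2 (percentile 1.23), and 9 of 15 did in MUT (14.9). At a 2 kb window the WT count was 11. These counts depended on the threshold. At a −log10 q of 5 or more 5729 genes had an end region in WT and 532 in MUT, with 9 and 0 STAT5 targets. The same q stood for different heights in the 2 lists. The WT region of 18 fragments at ALK had a −log10 q of 8.58, the MUT region of 22 at ESPL1 one of 4.76. These counts at 1 q limit do not compare binding at a matched height. With each list cut to the 35096 regions of the shortest of the 4, sgTET1, there were 3107 and 5632 genes, with 4 and 11 STAT5 targets.

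The remaining lists lay nearer to random lists. B-lineage genes numbered 16 of 22 in WT (percentile 41.2) and 16 of 22 in MUT (44.8). DNA methylation genes numbered 11 of 12 in WT (89.1; DNMT3A and GADD45A highest) and 10 in MUT (73.4; DNMT1 and DNMT3A highest). CpG-island developmental genes numbered 13 of 15 in both (85.8 and 88.6) and HOXA and MEIS1 genes 5 of 6 in both (78.2 and 80.6). Housekeeping and ribosomal genes numbered 12 of 15 in both (69.2 and 74.8). Cytokine receptor and JAK genes numbered 9 of 12 in WT (44.8) and 10 in MUT (72.4). Markers of T and NK cells, at 9 and 10 of 12 (50.1 and 77.6), myeloid cells, at 8 and 8 of 11 (48.9 and 55.1), and erythroid cells, at 5 and 5 of 8 (37.6 and 43.5), lay between percentiles 37.6 and 77.6.

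The highest gene-end regions in WT were at NBPF1 with 37 fragments, C8orf33 with 34, DGCR8 (a microRNA-processing factor, which shares an end with TRMT2A) and TAF2 (a subunit of TFIID) with 33, FCMR (the Fc receptor for IgM, beside IL24) with 31 and TRIB1 with 30. All 6 had MUT regions within 1 kb. In MUT the highest were at LRRC14 with RECQL4, a DNA helicase gene (43 fragments; chromosome 8, 144518018 to 144518848), and, with 38 each, at EXOSC4 and GPAA1, where 1 region reaches an end of both, GRINA and TRAPPC9, all on chromosome 8 and all with WT regions within 1 kb. Gene-end regions without a counterpart within 1 kb were lower. In WT they were highest at MAGEL2, with 21 fragments (13 to 32.1; chromosome 15, 23642724 to 23643002), ABI3BP with TFG (20), DCP2 with MCC (19) and ALK (18), a receptor tyrosine kinase. In MUT they were highest at ESPL1, which encodes separase, with 22 fragments (13.8 to 33.3; chromosome 12, 53266952 to 53267331), ABHD13 with LIG4 (21), CCDC3 with OPTN (21) and ADGRL4 (20). The smallest heights listed were 6 and 7 fragments.

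At the study's genes, CD72 had 44 WT and 30 MUT regions in the gene or within 10 kb, the highest with 17 fragments in WT (9.90 to 27.2) and 21 in MUT (13 to 32.1). JCHAIN had 4 and 3, with 13 fragments in WT (6.92 to 22.2) and 11 in MUT (5.49 to 19.7) at the highest. STAT5A had 33 and 30 regions, STAT5B had 54 and 48, and TET1 had 47 and 23. These counts were not set against the length of each gene. Outside chromosomes 8 and 18 the lists held 155 WT and 107 MUT regions per Mb. The intervals of the highest regions overlapped between WT and MUT at CD72 and JCHAIN.

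MUT overlapped 44.9% of WT regions (44.7 to 45.0; circular shifts 6.98%, local shifts 16.9%), and WT overlapped 63.1% of MUT regions (62.9 to 63.3; 9.96% and 23.8%). All 200 circular shifts lay below the observed share in each direction. The shares were 2.94% and 79.5% at a −log10 q of 5 or more, which left 74407 WT and 2406 MUT regions. That limit lay at a greater height in MUT than in WT, so these 2 shares are not at matched heights. The WT list was 1.45 times as long as the MUT list. At matched heights the order changed. The ratio of WT to MUT regions was 1.01 at 10 or more fragments, 0.762 at 12 or more and 0.359 at 20 or more. In multiples of each background it was 1.37 at 6, 1.59 at 8, 1.19 at 10 and 0.903 at 12. Heights are whole numbers, so these multiples match only roughly between the lists. Outside chromosomes 8 and 18, 7.96% of WT regions (7.88 to 8.04) and 10.9% of MUT regions (10.8 to 11.0) lay at a gene end, against 5.66% and 6.32% for local shifts. Among regions of 20 to 29 fragments the shares were 14.8% of 871 WT regions (12.5 to 17.3) and 26.2% of 4610 MUT regions (25 to 27.5). At 30 or more fragments they were 3.90% of 77 WT regions (0.811 to 11.0) and 6% of 150 MUT regions (2.78 to 11.1).

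**Figure D2:**
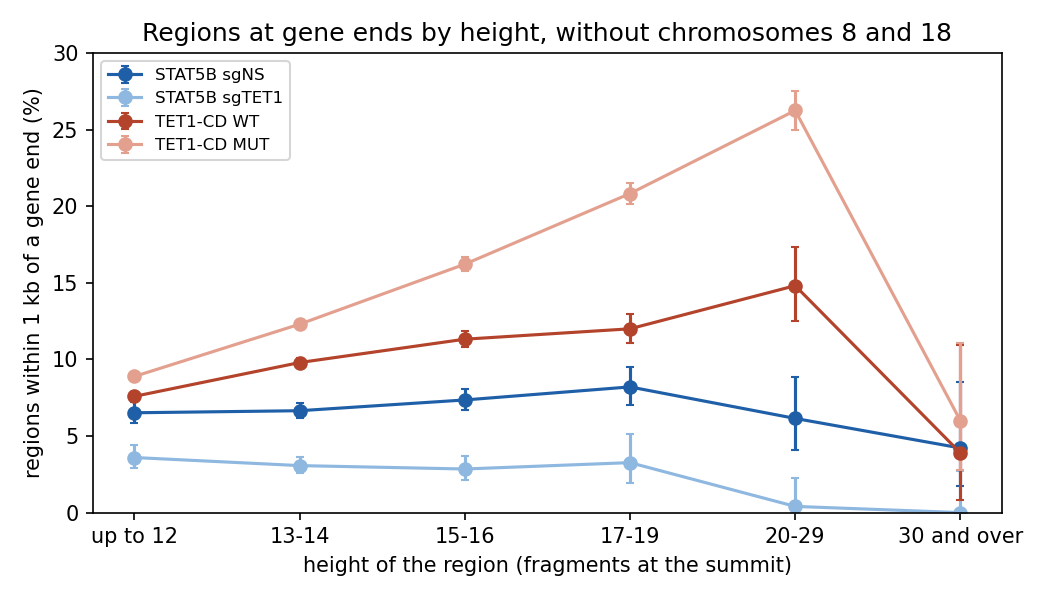
Share of regions within 1 kb of either end of a protein-coding gene, in percent, by the height of the region in fragments, for the 4 lists without chromosomes 8 and 18; bars are exact 95% intervals for counting error in 1 library each. The share rises with height in TET1-CD MUT to 26.2% at 20 to 29 fragments and in WT to 14.8%, then falls to 6% and 3.90% at 30 or more, and is 6.15% in STAT5B sgNS and 0.403% in sgTET1 at 20 to 29 fragments.

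The third comparison asked where STAT5B and the TET1 catalytic domain lay at the same places. TET1-CD WT overlapped 40.4% of sgNS STAT5B regions (40.02 to 40.9) and MUT overlapped 31.8% (31.4 to 32.2). Circular shifts gave 9.74% and 7.50%, and local shifts 21.7% and 17.4%. For sgTET1 the shares were 37.1% by WT and 28.4% by MUT. At gene ends outside chromosomes 8 and 18, 55.4% of 1665 sgNS regions were overlapped by WT and 50.3% by MUT (local shifts 26.3% and 22.3%), and away from them 37.4% and 28.5% (16.5% and 12.96%). The ratios to local shifts were thus similar at gene ends and away from them, 2.11 and 2.27 for WT and 2.26 and 2.195 for MUT. With the lists cut to equal length, the WT and MUT shares of sgNS fell to 15.1% and 12.8%. Of the 2062 genes with an sgNS end region, 1921 also had a WT one and 1898 a MUT one, where lists independent within the 2 sets of chromosomes would share 1501 and 1476.

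Within 1 kb of the STAT5B regions at CISH with MAPKAPK3 there were 4 WT and 2 MUT regions, and at SOCS2 2 of each. At BCL6, KLF7 and SLFN12L there were 0 of either. Of the 248 sgNS regions of 20 or more fragments that were absent from sgTET1, 96 were overlapped by WT (38.7%, 32.6 to 45.1; local shifts 21.9%) and 84 by MUT (33.9%; 18.3%). At 30 or more fragments, 3 of 36 were overlapped by WT (8.33%, 1.75 to 22.5; local shifts 23.3%) and 5 by MUT (13.9%; 19.5%). Of the 341 in both STAT5B lists, 225 were overlapped by WT (66.0%, local shifts 10.5%) and 233 by MUT (68.3%, local shifts 9.93%). Of these 341, 208 overlapped both TET1-CD lists and 6 lay at a gene end.

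**Figure D3:**
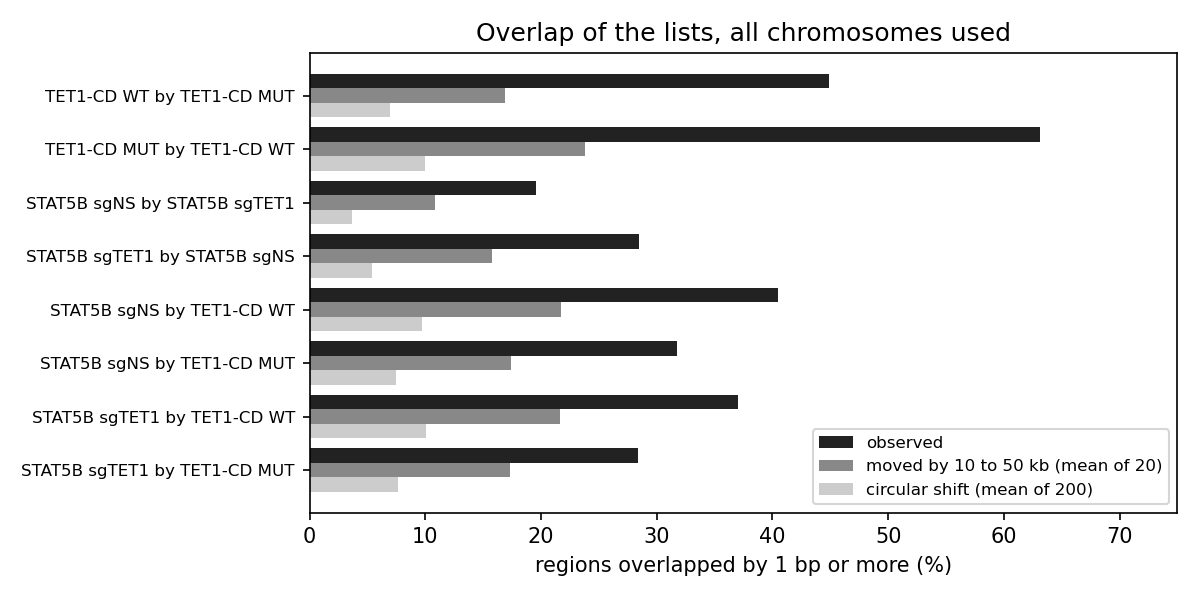
Share of the regions of the first list that the second list overlaps by 1 bp or more, in percent, for 8 ordered pairs of lists; dark bars are the observed shares, mid-grey bars the mean of 20 sets of regions moved by 10 to 50 kb, and light bars the mean of 200 circular shifts. Each observed share is above both, for example 40.4% against 21.7% and 9.74% for STAT5B sgNS by TET1-CD WT.

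STAT5B regions of control cells that a TET1-CD WT region overlapped were also found in TET1-knockout cells more often than those without one, 25.8% of 20390 against 15.3% of 30024. In the deciles of −log10 q, the 74.3% of sgNS regions with a q of 1 shared a bin, and bins had equal weight. An average over them therefore gives higher regions more weight than the raw shares do. Averaged over these deciles, the difference was 12.4 percentage points (jackknife interval 2.19 to 22.7). With MUT in place of WT it was 12.9. The interval included 0 without deciles (10.5; −1.56 to 22.5), with deciles of fold (8.96; −0.0812 to 18.004) and at gene ends only (14.98; −0.982 to 30.9). Outside chromosomes 8 and 18, 6.90% of regions with and 3.69% of regions without a WT region were found again. The average over deciles there was 6.45 points with WT (1.82 to 11.1) and 8.68 with MUT. Places listed with either antibody would raise this difference. Of the sgNS regions of 50 or more fragments there, 92.2% were found again, and WT and MUT each overlapped 93.75%. The difference alone does not tie kept STAT5B binding to TET1-CD.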

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

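All tests of explanations in this part were chosen after the results were seen. Listed rows outside the chromosomes compared were set aside as data no comparison used. On unplaced and alternative contigs there were 446 rows in STAT5B sgNS, 480 in sgTET1, 710 in TET1-CD WT and 634 in MUT. On the mitochondrial genome the largest fold was 57.6 in sgNS, 51.2 in sgTET1, 72.6 in WT and 42.3 in MUT, from 1, 1, 4 and 4 rows. No control list was used here to set these against.

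The STAT5B regions of 31 to 60 fragments at BCL6, CISH, BCL2L1, SOCS2, PIM1 and CCND3 in control cells had no region within 1 kb in TET1-knockout cells, while MYC had regions of similar height in both. MYC lies on chromosome 8. On chromosomes 8 and 18, regions of 20 or more fragments were 23.5 (sgNS) and 19.6 (sgTET1) times as dense as elsewhere. The MYC regions cannot be told apart from that excess. A lower depth of the sgTET1 library is argued against, since its background was 0.966 times that of sgNS. A weaker STAT5B immunoprecipitation in that library is consistent with the gene-end share of its regions, 0.747 times that of local shifts where sgNS had 1.42, but a general loss of STAT5B from chromatin in these cells would give the same value. Binding that depends on TET1 at the same places stays open. The Flag lists map an expressed, tagged catalytic domain and not the TET1 that was knocked out. Overlap with them cannot show where that TET1 bound, so the next values cannot decide it. TET1-CD WT overlapped 38.7% of the strong sgNS regions that sgTET1 lacked, above local shifts. It overlapped 8.33% of the highest 36 of them, below local shifts. The 66.0% of those in both lists is no fair measure to set beside these. Of those 341 regions, 208 overlapped both TET1-CD lists, and places listed with either antibody would raise that share. The same limit holds for sgNS regions found again outside chromosomes 8 and 18. There 6.90% of regions with an overlapping WT region and 3.69% without one were found again (6.45 percentage points averaged over deciles of −log10 q, and 8.68 with MUT). With 1 library per condition, these last explanations cannot be told apart.

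STAT5B regions were denser on chromosomes 8 and 18 than elsewhere, 13.5 times in sgNS and 33.8 times in sgTET1. A higher read level on these chromosomes, called against a single genome-wide background, may contribute. The Flag lists from the same cells were denser there too, by 1.31 times at the least. In the full lists sgNS and sgTET1 had nearly equal numbers there (a ratio of 1.02). At 20 or more fragments they did not (1114 and 603, a ratio of 1.85). The size of the excess depended on height: at 10 or more fragments it was 13.5 times in sgNS, 33.8 in sgTET1, 1.74 in WT and 1.41 in MUT, and at 20 or more 23.5, 19.6, 21.6 and 6.47. STAT5B binding that prefers these chromosomes stays open: sgNS regions there lay at gene ends 1.12 times as often as local shifts, against 1.42 elsewhere, and sgTET1 regions 0.845 times, against 0.747, and binding away from gene ends is not covered by that test. At 30 or more fragments the STAT5B lists had a density ratio of 1.27 in sgNS and 0.369 in sgTET1, from 17 and 4 regions there.

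The TET1-CD WT list was 1.45 times as long as the MUT list. Peak calling with another scale and smallest height in each list could contribute, since the ratio was 0.762 at 12 or more fragments. It was 1.37 at 6 times each background, 1.59 at 8 times and 0.903 at 12 times. Heights are whole numbers, so such limits match only roughly, and at 8 times the limit reached lay at a higher multiple in MUT. No matched limit decides between peak calling and a difference in binding. The design also allows that difference, which was not tested apart from these ratios.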

How the results depend on the processing

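Motif and CpG content at summits, with their alternatives, were not run, since they need a genome sequence. No paired analysis was possible because each condition has 1 library and the labels carry no replicate numbers. The retention difference at a −log10 q of 5 or more gave no value, with fewer than 20 regions of each kind per decile. Its other 8 values kept their direction and lay inside the interval of the reported value, from 6.45 without chromosomes 8 and 18 to 20.2 with lists of equal length. For 3 of them the interval included 0, unlike that of the reported value (2.19 to 22.7): no deciles (−1.56 to 22.5), deciles of fold (−0.0812 to 18.004) and gene-end regions only (−0.982 to 30.9). All 35 alternative overlap shares, 14 of 16 gene-end shares, 18 of 28 counts of regions and genes and 83 of 226 gene list counts moved beyond the counting error of the reported value or, for counts, by more than 1.5 times. Of these, the gene-end shares of sgNS and sgTET1 at a −log10 q of 5 or more had wide intervals that include the reported 4.63% and 2.12% (2.27 to 9.13 and 0 to 2.46). Where the window, the overlap rule or the list length changed, the construction moves the value; for the others the cause was not tested. The choices made after seeing the data were leaving out chromosomes 8 and 18, a q of 0.05 or less, matched height limits, the local shift, and strong STAT5B regions, by themselves and within 10 kb of genes. What depth limits was not tested. The STAT5B lists had a q of 1 for 74.3% and 75.5% of regions at backgrounds of 3.30 and 3.19 fragments, and the Flag lists for 0% at 1.49 and 1.66.

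At a −log10 q of 5 or more there remained 183 sgNS, 148 sgTET1, 74407 WT and 2406 MUT regions. This limit lay at a greater height in MUT than in WT, so their values at it are not matched in height. Of these 4.92%, 0%, 9.22% and 20.8% lay at gene ends, at 10, 0, 5729 and 532 genes. MUT then overlapped 2.94% of WT regions and WT 79.5% of MUT regions, sgTET1 overlapped 61.2% of sgNS regions and sgNS 77.0% of sgTET1 regions, WT and MUT overlapped 63.4% and 50.3% of sgNS regions, and WT 71.6% of sgTET1 regions. At a q of 0.05 or less there were 1703 sgNS, 986 sgTET1 and 109170 MUT regions. Without chromosomes 8 and 18, sgNS had 24181 and sgTET1 9437 regions, and 298 genes had an sgTET1 end region. Gene-end shares were then 6.89%, 3.05%, 7.96% and 10.9% in sgNS, sgTET1, WT and MUT. The 7 overlap shares, in the order just given, became 43.7%, 61.3%, 4.93%, 12.9%, 38.7%, 29.95% and 32.7%. With lists of equal length they were 48.9%, 49.3%, 21.8%, 22.5%, 15.1%, 12.8% and 13.7%, gene-end shares 9.33% in WT and 18.2% in MUT, and genes 3107 and 5632. With 50% of the region covered the overlap shares were 34.8%, 49.4%, 13%, 20.8%, 29.8%, 22.7% and 28.1%, and with summits within 200 bp 37.7%, 54.2%, 15.8%, 22.7%, 32.5%, 24.8% and 29.1%. A window of 2 kb gave gene-end shares of 9.04%, 4.20%, 12.4% and 15.8%, and 3686 sgNS and 1044 sgTET1 genes.

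Of the gene list counts, STAT5 targets in sgTET1 fell to 0 without chromosomes 8 and 18, by gene ends and by strong regions within 10 kb, while sgNS had 5 and 7, and apoptosis genes in sgTET1 fell to 1 by gene ends. At a −log10 q of 5 or more, the sgNS list gave 3 for STAT5 targets and 0 for B-lineage, study genes, cytokine receptor, cell cycle, apoptosis and housekeeping. At a −log10 q of 5 or more, the sgTET1 list gave 0 for STAT5 targets, developmental, cell cycle, apoptosis and T and NK cell. At a −log10 q of 5 or more, the WT list gave 9 for STAT5 targets and apoptosis, 6 for B-lineage, 5 for cell cycle and T and NK cell, 3 for study genes, DNA methylation, HOXA and MEIS1 and myeloid, 2 for cytokine receptor and erythroid, 1 for developmental and 0 for tissue-restricted. At a −log10 q of 5 or more, the MUT list gave 1 for cell cycle, housekeeping and erythroid and 0 for STAT5 targets, B-lineage, study genes, cytokine receptor, DNA methylation, HOXA and MEIS1, developmental, apoptosis, T and NK cell, myeloid and tissue-restricted. With lists of equal length, the sgNS list gave 3 for housekeeping, 1 for B-lineage and cytokine receptor and 0 for study genes. With lists of equal length, the WT list gave 6 for apoptosis, 4 for STAT5 targets and cell cycle, 3 for DNA methylation and housekeeping, 2 for B-lineage, HOXA and MEIS1 and myeloid, 1 for study genes, cytokine receptor, developmental and T and NK cell and 0 for erythroid and tissue-restricted. With lists of equal length, the MUT list gave 8 for apoptosis, 7 for housekeeping, 6 for B-lineage, 5 for cell cycle, 4 for DNA methylation and developmental, 3 for HOXA and MEIS1 and myeloid, 2 for T and NK cell, 1 for cytokine receptor and erythroid and 0 for tissue-restricted. With a window of 2 kb, the sgNS list gave 9 for housekeeping, 6 for B-lineage and cell cycle and 1 for DNA methylation, T and NK cell and myeloid. With a window of 2 kb, the sgTET1 list gave 3 for cell cycle, 2 for B-lineage and T and NK cell and 1 for cytokine receptor. With a window of 2 kb, the WT list gave 11 for tissue-restricted.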

Other observations

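The following STAT5B regions away from gene ends, which sgTET1 lacked, were picked from the 40 highest after their values were seen, and no shared function was tested. In sgNS a region of 70 fragments (54.6 to 88.4) lay in ERICH6B (chromosome 13, 45546114 to 45546528), the highest of them. A region of 39 fragments lay 5122 bp from HEMK1 and near CISH (chromosome 3, 50601138 to 50601493). A region of 34 fragments lay 21140 bp from SOCS1 (chromosome 16, 11233121 to 11233527), a preset STAT5 target that had no STAT5B region within 10 kb. Others lay in GNA15 (38 fragments), a G-protein subunit of blood cells, HDAC7 (32), a histone deacetylase, and SKI (32). No sgTET1 region lay within 1 kb of any of these.

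Of the 130 sgNS regions of 30 or more fragments found in both STAT5B lists outside chromosomes 8 and 18, 109 also overlapped both TET1-CD lists and 0 lay at a gene end. Of the 36 that sgTET1 lacked, 7 lay at a gene end and 3 overlapped both TET1-CD lists. The highest of the 130 were those beside the centromeres of chromosomes 16 and 3, with 236 to 291 fragments in sgNS and regions in all 4 lists. Places listed with both antibodies need not be bound by both proteins, and no control list was used here to check them.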
